A study of Caenorhabditis elegans with 4 samples.

How the data were processed

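Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on formaldehyde-fixed mixed-stage embryos of Caenorhabditis elegans strain N2, the wild-type laboratory strain, with a rabbit control IgG that has no intended target in the worm. Per the labels' protocols, embryos were fixed in 2% formaldehyde for 30 minutes, chromatin was sheared by sonication, 2 mg of extract went into each immunoprecipitation, and 10% was kept as input DNA. The series holds 4 samples, 2 IgG ChIP libraries and 2 input DNA libraries. The labels name a pair of sequencing instruments and a pair of sites without saying which served which library, so no batch could be formed. The labels do not say that the replicates came from separate cultures.

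The authors deposited 3 peak lists that are used here, 1 for each IgG library and 1 combined list for the series. Per the file headers, coordinates are in WormBase build WS220, and per the source field of the files the authors called the replicate lists with MACS and the combined list with MACS v2. The aligner, the control used for calling, read filters, the calling threshold and the way in which the replicates entered the combined list are not given in the sources used here. Each deposited peak carries a score from the authors' peak caller, and the files do not name its scale. Replicate scores run from 50.01 to 3233.06 and combined scores from 1.31 to 52.39. Of the replicate 2 peaks, 7 hold the identical score 3100, so their order among themselves is undefined. Scores were used here to rank, filter and describe peaks within one list and were never compared between lists. Read counts per library were not used here, so the depth of each library is unknown. The number of peaks a library yields depends on depth and on the caller's threshold, and no difference in signal strength between the libraries can be read from it.

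The peak lists were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and drawn with Matplotlib 3.10.9. Within each list no peaks overlapped. Peaks shared at least 1 bp to count as overlapping. Overlap of the replicate lists was tested with 10000 random placements of the replicate 1 peaks, each within its own chromosome and with its own width (one-sided permutation test). Scores of shared and unshared peaks were compared within each list by a two-sided permutation test of the difference in medians (100000 permutations), adjusted by the Benjamini-Hochberg method over the 2 lists. The share of combined peaks on each of the 6 nuclear chromosomes was set against that chromosome's share of the summed extent by a two-sided exact binomial test, adjusted over the 6 chromosomes. The extent of a chromosome was taken as the highest peak end in any of the 3 lists, since no WS220 chromosome lengths were used here. Each chromosome was divided into 3 sections of equal length, and the share of peak midpoints in the central section was tested in the same way against an even spread, for the 5 autosomes together and for the X. Values for single chromosomes were added after the autosomal value was seen. Intervals are exact Clopper-Pearson 95% intervals. They treat peaks as independent and cover counting error only. All of these tests describe the lists at hand, with peaks as the units. They do not measure variation between cultures.

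Simulated lists were used to check the tests. With no true overlap, 2.5% of 200 simulated replicate 1 lists of 153 peaks passed the 0.05 threshold of the permutation test, and with 20% of peaks copied from replicate 2, 100% did. For the X share over 825 peaks, 6% of 200 simulations passed the binomial test without adjustment with no difference, and 100% with a 1.5-fold excess. The simulated replicate 1 lists and the X simulations treated peaks as independent. They therefore do not show how often these tests pass by chance when peaks cluster. For the scores, 6.5% (replicate 1) and 3% (replicate 2) passed with no shift, and 100% with a shift of 1 on the log2 scale, also without adjustment. The X and score tests reported below are adjusted, so these rates do not describe them directly. For the X share and the scores, smaller effects were not simulated. The 100% values therefore do not show how often a smaller difference would pass.

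The regions named in the text were fixed before the data were examined as the 20 highest scoring combined peaks that overlap a peak in both replicate lists. The same rule would have named the genes at these peaks and members of preset gene classes. The gene table at hand describes assembly WBcel235, another build than WS220, so no gene was assigned to any peak, and the planned tests of genomic features, gene classes and base composition were not run. Alternatives covered the overlap criterion, the peaks at or above the median score of each list, merging within 1 kb, the highest scoring peak per 10 kb, circular shifts of the peaks, and each replicate list in place of the combined one. No files of the input libraries were used here.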

Results

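IgG ChIP-seq measures where chromatin is recovered without a specific antibody target, and such a library serves as the negative control for ChIP with specific antibodies. Peak lists were examined from 2 IgG libraries of mixed-stage N2 embryos, together with the combined list of the series. Replicate 1 held 153 peaks covering 153353 bp, and replicate 2 held 789 peaks covering 680064 bp. Replicate 2 thus had 5.16 times as many peaks and 4.43 times the covered length. The combined list held 831 peaks covering 269364 bp, of which 825 were nuclear and 6 mitochondrial. Combined peaks were narrower, with a median width of 226 bp against 536 bp in replicate 1 and 469 bp in replicate 2. Peaks covered 0.153%, 0.680% and 0.268% of the nuclear extent in replicate 1, replicate 2 and the combined list. The sequencing depth of the libraries is unknown, and with a single list per library the difference in peak number has no replicate check.

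**Figure D1:**
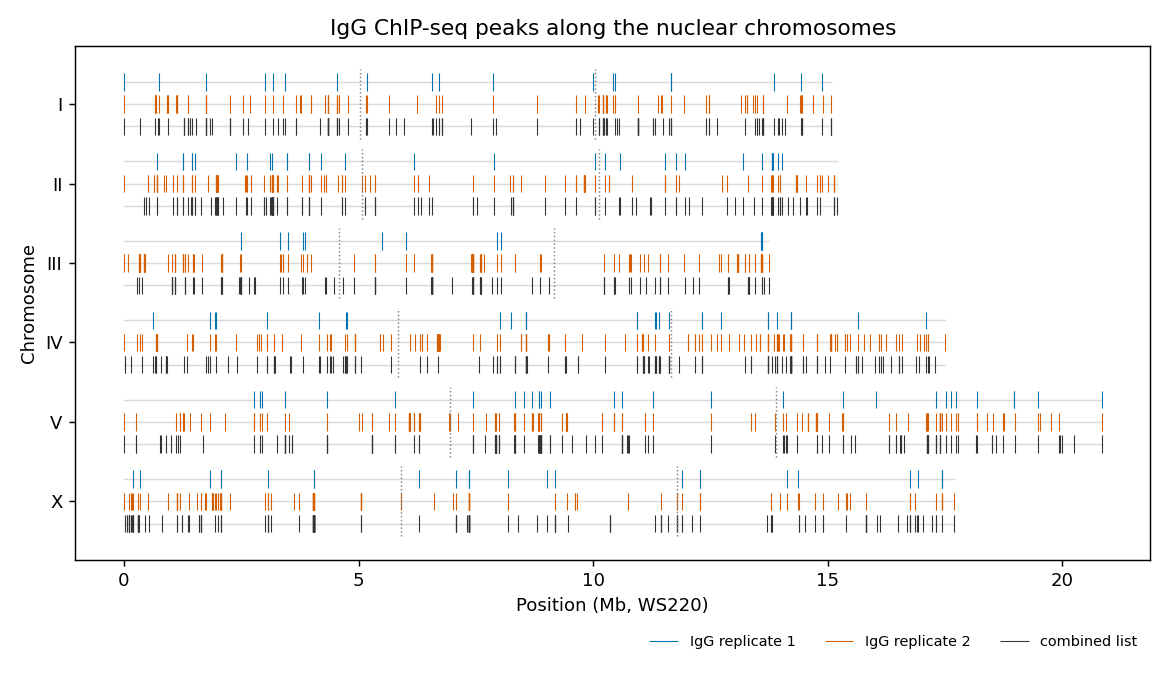
Peaks along the 6 nuclear chromosomes, with position in Mb (WS220) on the x axis and chromosome on the y axis. Each tick is the midpoint of a peak in IgG replicate 1 (153 peaks), IgG replicate 2 (789 peaks) or the combined list (825 nuclear peaks), and dotted lines divide each chromosome into 3 sections of equal length.

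The first question was whether a control IgG gives peaks at the same places in both libraries. Of the 153 replicate 1 peaks, 114 overlapped a replicate 2 peak, a share of 74.5% (95% interval 66.8 to 81.2%). Random placement gave a mean of 1.89 shared peaks and at most 8, so the observed number was 60.4 times the mean of the placements (one-sided permutation test, p = 0.0001, the smallest that 10000 placements can give). Circular shifts of the replicate 1 peaks, which keep neighbouring peaks together, gave a mean of 1.92 and at most 26. Very small shifts were not excluded, so the highest value may come from a shift that nearly restored the original positions. Seen from replicate 2, 124 of 789 peaks were shared, or 15.7% (13.2 to 18.4%), against a mean of 2.14 under random placement (permutation p = 0.0001, again the smallest possible). Random placement spreads peaks evenly over a chromosome, so these p-values speak only against an even spread. No input files were used here, so whether input DNA would give peaks at the same places is unknown. The replicate lists had 126674 bp in common, which was 82.6% of the replicate 1 and 18.6% of the replicate 2 covered length. The 10 highest scoring replicate 1 peaks all overlapped a replicate 2 peak. Of the 10 highest scoring replicate 2 peaks, 3 overlapped a replicate 1 peak.

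**Figure D2:**
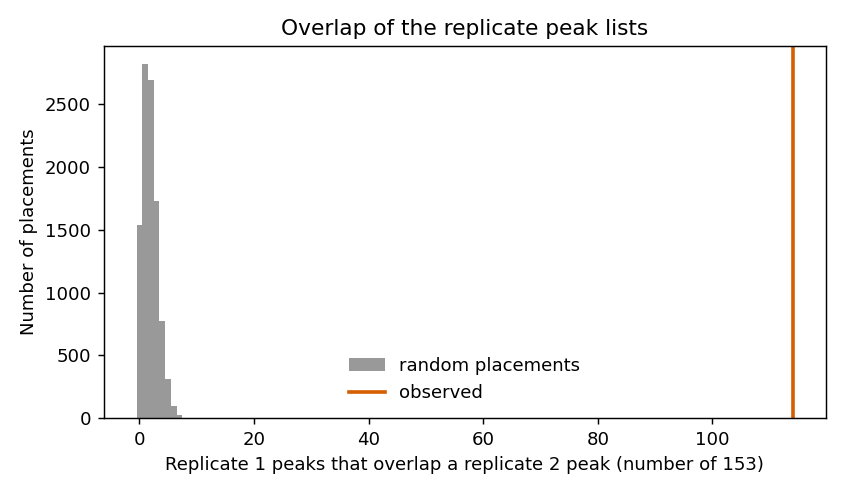
Number of the 153 replicate 1 peaks that overlap a replicate 2 peak (x axis) in 10000 random placements (grey bars, y axis in placements) and as observed (orange line). The observed 114 lies far above the highest of these placements, 8, and above the highest of 10000 circular shifts, 26 (not drawn).

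The 20 strongest combined peaks found in both replicates lay on chromosome IV (7 regions), chromosomes II and III (4 each), chromosome V (3) and chromosome I (2). None was on the X. The highest combined score, 52.39, belonged to a 309 bp peak on chromosome III at 8043732 to 8044040. It matched a 448 bp peak with a score of 267.27 in replicate 1 and a 383 bp peak with a score of 313.44 in replicate 2. About as high, at 48.72, was a 1292 bp peak on chromosome III at 7941633 to 7942924. That region also held the highest score of the whole replicate 1 list, 2057.16 over 1300 bp, and scored 1600.87 over 1249 bp in replicate 2. A further pair on chromosome III lay at 3818748 to 3819669 (combined score 18.89) and at 3499839 to 3500145 (also 18.89). No gene was assigned to any of these regions, since the gene table used here is of another genome build.

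On chromosome IV the strongest shared peak lay at 4749930 to 4750171, with a combined score of 24.03, followed by 3050722 to 3050956 at 19.32 and 15636102 to 15636820 at 18.69. Chromosome IV also held a pair of named peaks close to each other, at 8572773 to 8573036 (11.64) and 8575993 to 8576752 (12.64). At the second of these, the overlapping replicate peaks were nearly identical in extent, 2119 bp in replicate 1 and 2114 bp in replicate 2. The remaining named peaks of chromosome IV were at 14208070 to 14209033 (15.74) and 17087364 to 17087685 (14.29). Chromosome II carried named peaks at 10248306 to 10248551 (20.57), 6185234 to 6186422 (16.34), 11759187 to 11759682 (15.57) and 11534487 to 11535022 (13.75). The peak at 6185234 had the second highest score of replicate 1, 610.48, and scored 596.44 in replicate 2. Those of chromosome V began at 2777497 (15.75), 17629205 (12.50) and 8853310 (11.20), and those of chromosome I at 5176243 (15.50) and 2995933 (11.43).

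Shared peaks scored higher than unshared ones in replicate 2. There the median score was 177.85 for the 124 shared peaks and 96.40 for the 665 others, a difference of 81.45 (two-sided permutation test, adjusted p = 2e-05, from the smallest p that 100000 permutations can give). In replicate 1 the medians were 80.9 for 114 shared and 67.5 for 39 unshared peaks, a difference of 13.4 that did not pass the test (permutation test, adjusted p = 0.054). Shared peaks were also wider, with medians of 619 bp against 429 bp in replicate 2 and 598.5 bp against 397 bp in replicate 1. With an overlap of at least 50% of the shorter peak, the replicate 1 difference was 15.04 and passed (permutation test, adjusted p = 0.028), and with peaks within 500 bp counted as shared it was 12.6 and did not (adjusted p = 0.079).

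Most combined peaks overlapped a replicate 2 peak, and replicate 2 held 5.16 times as many peaks as replicate 1. Of its 831 peaks, 158 overlapped peaks of both replicates (19.0%, 16.4 to 21.8%), 365 overlapped replicate 2 alone (43.9%, 40.5 to 47.4%) and 30 overlapped replicate 1 alone (3.61%, 2.45 to 5.11%). The remaining 278 peaks overlapped neither list (33.5%, 30.2 to 36.8%). Their median combined score was 3.75, against 5.62 for peaks seen in both lists, 6.33 for replicate 1 alone and 3.93 for replicate 2 alone. In the other direction, 127 of 153 replicate 1 peaks (83.0%, 76.1 to 88.6%) and 349 of 789 replicate 2 peaks (44.2%, 40.7 to 47.8%) held a combined peak. The 440 replicate 2 peaks without one had a median replicate 2 score of 85.8, against 155 for the others. All 40 of the highest scoring replicate 2 peaks held a combined peak, and 100 replicate 2 peaks held at least 2. These shares are descriptions and were not tested. The source fields name MACS for the replicate lists and MACS v2 for the combined list.

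In the full combined list, the share of peaks on each nuclear chromosome was 0.85 to 1.10 times its share of the extent. Chromosome IV and the X each held 159 of 825 nuclear combined peaks, 19.3% (16.6 to 22.1%), against 17.5% and 17.7% of the extent. Chromosome V held 146 peaks, 17.7% (15.2 to 20.5%), against 20.8% of the extent. Chromosomes I, II and III held 15.5%, 15.4% and 12.8%, against 15.1%, 15.2% and 13.7% of the extent. In the full combined list no chromosome passed the two-sided exact binomial test after adjustment, where the smallest adjusted p was 0.15, for chromosome V, and 1 chromosome had an unadjusted p under 0.05 (V, p = 0.026). On the X, 29 of the 159 peaks lay in a dense run between 4033179 and 4056399, and without that run the X held 16.3% of the peaks, a comparison chosen after seeing the data. Replicate 2 alone gave 14.6% of peaks on the X and 12.3% on chromosome I (exact test, adjusted p = 0.043 for both), and 17.2% on chromosome III and 21.04% on chromosome IV (adjusted p = 0.03 for both). Replicate 1 alone gave 16.99%, 13.1%, 8.50% and 20.3% for these 4 chromosomes, of which none passed. Among combined peaks in both replicate lists, chromosomes I and III each held 12 of 158 (7.59%), of which chromosome I passed (exact test, adjusted p = 0.043) and chromosome III did not (adjusted p = 0.062). Whether the replicates differed in these shares was not tested.

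**Figure D3:**
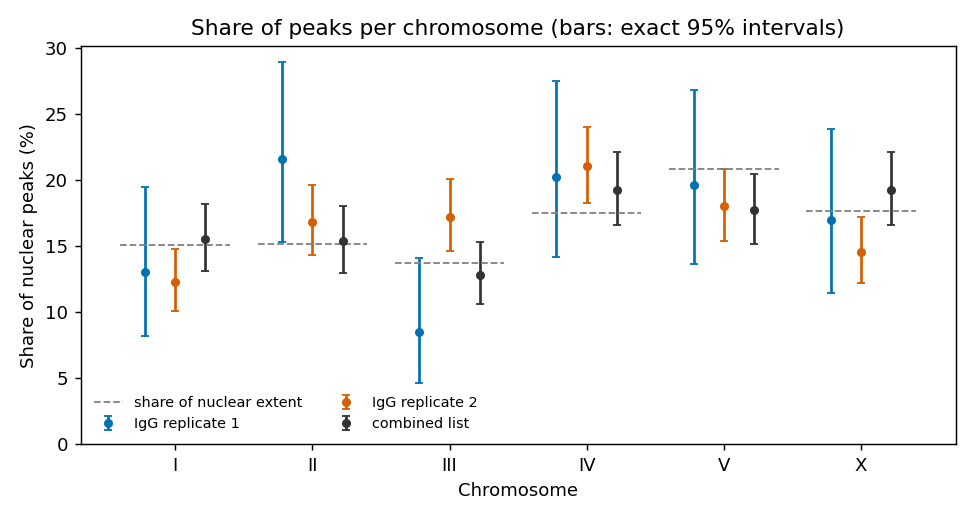
Share of nuclear peaks per chromosome (y axis, %) in each list, with exact 95% intervals, beside each chromosome's share of the nuclear extent (dashed lines). In the combined list the X held 19.3% of peaks and chromosome V 17.7%, and no combined share passed the test.

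In the full combined list, central parts of chromosomes I and II carried few peaks. C. elegans autosomes have gene-dense centres and repeat-rich arms. With each chromosome divided into 3 sections of equal length, an even spread would put 33.3% of midpoints in the central section. On the 5 autosomes together, 184 of 666 combined peaks lay there, 27.6% (24.3 to 31.2%, two-sided exact binomial test, adjusted p = 0.0035). On chromosome I the central section held 21 of 128 peaks, 16.4% (10.5 to 24.0%, exact test, adjusted p = 0.00013 over 6 chromosomes), and on chromosome II 24 of 127, 18.9% (12.5 to 26.8%, exact test, adjusted p = 0.0013). Chromosomes III, IV and V held 34.0%, 31.4% and 36.3% in the central section and did not pass (exact test, adjusted p = 0.92, 0.81 and 0.72). On the X it was 42 of 159 peaks, 26.4% (19.7 to 34.0%, exact test, adjusted p = 0.065 over the planned pair of tests).

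Chromosome II held few central peaks in each replicate alone, 3 of 33 (9.09%) in replicate 1 and 29 of 133 (21.8%) in replicate 2 (exact test, adjusted p = 0.015 and 0.0085). Chromosome I passed in replicate 2, with 11 of 97 (11.3%, exact test, adjusted p = 4.7e-06), and not in replicate 1, with 5 of 20 (adjusted p = 0.85, exact test). With the highest scoring peak per 10 kb counted alone, the central shares of I and II were both 20.7% (exact test, adjusted p = 0.042 for each), and that of chromosome IV was 24.0% (exact test, adjusted p = 0.083). For the autosomes together, replicate 2 alone passed (26.1%, exact test, adjusted p = 0.00012) and replicate 1 alone, with 36 of 127 peaks (28.3%), did not (exact test, adjusted p = 0.52). The calls on I and II were both lost at or above the median combined score, where chromosome I had 22% and chromosome II 18.3% of peaks in the central section (exact test, adjusted p = 0.3 and 0.08). They were also lost among combined peaks in both replicate lists, with 3 of 12 peaks on I and 3 of 25 on II (exact test, adjusted p = 0.91 and 0.19). On the X, replicate 2 alone had 24 of 115 peaks in the central section and passed (20.9%, exact test, adjusted p = 0.004 over the planned pair of tests). Replicate 1 had 8 of 26 (30.8%) and did not (exact test, adjusted p = 1). Chromosomes III, IV and V pooled held 33.8% in the central section (exact test, p = 0.83). The values for single chromosomes were computed after the autosomal value was seen, and the exact tests treat neighbouring peaks as independent.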

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

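The tests on the mitochondrial peaks were chosen after these peaks were seen. The combined list held 6 mitochondrial peaks, outside the comparisons of nuclear chromosomes, and neither replicate list held any. They lay at 4616 to 4909, 5099 to 5306, 8658 to 8817, 12152 to 12666, 13054 to 13222 and 13398 to 13751 of the mitochondrial genome. The last one, 354 bp wide, had a combined score of 45.59, the third highest of the list, while the other 5 scored between 1.94 and 4.03. In the C. elegans mitochondrial genome a large AT-rich non-coding region stands near the end of the usual numbering. Scores under the bar of the replicate lists are one candidate explanation. If each mitochondrial peak is matched to the 20 nuclear combined peaks nearest in score, the probability that all 6 lack a replicate peak was 0.00018, but this treats peaks of a single small molecule as independent. The strongest peak has no close match, since its 20 nearest nuclear peaks score from 12.64 to 52.39, and the 5 nuclear peaks that score at least 20 all have a replicate peak but are too few to decide, so this explanation stays open. Mitochondrial DNA left out of the replicate calls is another candidate. The 0 mitochondrial peaks in the replicate lists are the pattern to be explained, so they cannot test it, and a different background estimate would give the same count. No biological explanation was tested.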

How the results depend on the processing

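Over 100 comparisons of a tested result with an alternative, 63 left direction and side of the threshold in place. Of 8 comparisons of the untested combined-list shares, 5 stayed within the exact 95% interval. The overlap of the replicates passed under all 6 alternatives, with replicate 1 shares of 67.5 to 76.5% in the 5 that counted replicate 1 peaks. The score difference in replicate 2 passed under both alternative overlap criteria, and that in replicate 1 was 15.04 and passed with an overlap of at least 50% of the shorter peak, and was 12.6 and did not pass with peaks within 500 bp counted as shared. At or above the median combined score, 26.9% of peaks were in both lists, 39.1% in replicate 2 alone and 29.0% in neither. The autosomal share in the central section lost its call at or above that median (28.4%), among combined peaks in both replicate lists (31.97%), without chromosome I (30.3%) and without chromosome II (29.7%), and turned to 33.8% on III, IV and V. Single replicate lists gave 26.1 to 28.3% for the autosomes, where replicate 1 did not pass, and 20.9 to 30.8% for the X, where replicate 2 passed. With the highest scoring peak per 10 kb the X value was 21.3% and passed. On chromosomes I and II the central share lost its call at or above the median (22% and 18.3%) and in both lists (25% and 12%), and on I also in replicate 1 (25%). The central share of single chromosomes turned on III (30.8 to 30.9% in the replicate lists, 29.4% at or above the median, 29.9% merged within 1 kb, 25% in both lists, 27.9% per 10 kb), on IV (38.7% in replicate 1, against 30.1% in replicate 2, which did not turn, and 48.6% in both lists) and on V (30.99% in replicate 2, against 40% in replicate 1, which did not turn). Per 10 kb, V held exactly the even share of 33.3%. The X share of peaks fell below its share of the extent in the replicate lists (14.6 to 16.99%), merged within 1 kb (13.9%), per 10 kb (14.8%) and without the densest X run (16.3%). Of these, the replicate 2 value of 14.6% passed. Chromosome I held 12.3% of peaks in replicate 2 and 13.1% in replicate 1, 12.0% at or above the median and 7.59% among peaks in both lists. It passed in replicate 2 and among peaks in both lists. Chromosome IV, at 21.04%, passed in replicate 2 as well. Chromosome III held 8.50% in replicate 1, 17.2% in replicate 2, where it passed, and 7.59% among peaks in both lists. Chromosome II held 14.4% at or above the median, and chromosome V 24.1% among peaks in both lists. The cause of these shifts was not tested, and the replicate 1 list and the filtered settings hold fewer peaks than the combined list. The settings that left out a chromosome or the X run, and all values for the central section of single chromosomes, were chosen after seeing the data. The planned tests that need genes or sequence, and their alternatives, were not run. No paired analysis was possible because no files of the input libraries were used here. Depth per library is unknown, so an absent peak in replicate 1 cannot be read as absent signal.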

Other observations

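Regions in this part were picked after the lists were seen, and all tests here except the test of score within 5 groups of peak width were chosen after the result was known. Replicate 2 had a peak at the left end of each of the 6 nuclear chromosomes, starting at base 1 on I, II, III, IV and X and at base 4 on V. These peaks were 216 to 519 bp wide, with scores from 169.66 on III to 731.25 on I. Replicate 1 had such a peak on chromosome I alone, at 1 to 536 with a score of 87.71, and the combined list on chromosomes I (115 to 269) and V (143 to 298). The widest replicate 2 peak, 11126 bp, lay at the right end of chromosome I, at 15060224 to 15071349, with a score of 3100. Chromosome I of C. elegans carries its large ribosomal RNA gene array at its right end. The combined list had 3 peaks there with scores of 3.85, 3.85 and 4.04, and replicate 1 had 0. On chromosome V, replicate 2 had 5 peaks between 17115361 and 17132156, of which 2 scored 3100, the combined list had 9 peaks and replicate 1 had 0.

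Peaks also came in dense runs, here defined as peaks no more than 2 kb apart. The longest was on the X, where replicate 2 had 16 peaks between 4025960 and 4056479, against 31 combined peaks and 2 replicate 1 peaks in the same stretch. A second X run, at 7351653 to 7361296, held 15 combined, 10 replicate 2 and 3 replicate 1 peaks. The run on chromosome II at 3159892 to 3168176 held 13 combined, 9 replicate 2 and 1 replicate 1 peaks. A replicate 2 run of 8 peaks on chromosome II at 9808019 to 9820795 had 0 combined and 0 replicate 1 peaks.

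Random placement of the replicate 2 peaks put a peak start within the first 1 kb of at most 2 chromosomes in 10000 draws (one-sided permutation p = 0.0001, the smallest possible). The left-end peaks were noticed first in the same list, so this value restates the observation and does not test it independently. It speaks only against an even random placement of peaks. Chromosome ends carry telomeric repeats, so reads of repeated end sequence collected on few reference copies are a candidate explanation. Under it the input libraries would show the same depth, and without their reads it stays open. Replicate 1 had a peak at 1 of the 6 left ends. The right ends were not searched in the same way, so whether they carry such peaks as well is unknown.

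Wider peaks overlap more often and tend to score higher (rank correlation of score and width across peaks 0.78 in replicate 2 and 0.38 in replicate 1; peaks are not independent replicates), which could account for the higher scores of shared peaks. Within 5 groups of peak width, shared replicate 2 peaks still ranked 6.88 percentile points higher than the others (permutation p = 9e-05), down from 16.2 points without the width groups, and within 20 width groups the difference was 6.02 points (p = 0.00063). Width as grouped here therefore leaves part of the replicate 2 difference. In replicate 1 the difference within 5 groups was 6.69 points (permutation p = 0.13) and within 20 groups 8.39 points (p = 0.027), so width stays open as the cause there. The design names no biological difference between the replicates, and none was tested.

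None of the 20 strongest combined peaks in both replicate lists was on the X, against 36 of all 158 such peaks. This absence was noticed first, and the one-sided exact hypergeometric probability (p = 0.0038) was computed on the same 20 regions, so it restates the observation and does not test it independently. After merging peaks within 1 kb, 0 of the 20 strongest and 11 of all 98 shared regions were on the X (exact p = 0.069), which has the same limit. Whether the strongest shared regions avoid the X stays open.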
